A study of Mus musculus with 35 samples.

How the data were processed

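Total RNA of sorted mouse B cells and of lymphoid tumours was isolated with Tripure, amplified with the NuGen Ovation V2 system, labelled with biotin and hybridized to Affymetrix Mouse 430A2 arrays, per the labels. The deposited values are log2 probe set intensities that the authors made with RMA (background correction, quantile normalization and median polish, no version given). Which arrays were normalized together is not stated. The table held 22690 probe sets, among them 64 control probe sets. Of the others, 20380 had 1 gene symbol and were used, while 691 with several symbols and 1555 with none were left out. For the 4956 genes with more than 1 probe set, the probe set with the highest mean was taken, which gave 12393 genes. Arrays give no counts, so the number of arrays limits the precision. Whether replicates were separate mice or pools is not stated.

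Groups were taken from the labels. Each comparison was a contrast in limma with empirical Bayes moderation, fitted on the 22 normal arrays for comparisons of normal stages and on all 35 arrays for comparisons with tumours. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and only called genes, and lists that passed their test, are said to rise or fall. Signature genes of a stage had an adjusted p under 0.05 and a log2 difference of at least 1 against each of the 5 other stages. Lists of known genes for stages, processes and other cell types were fixed before the data were examined, as were the comparisons, the tests and most alternatives. The 26 lists with at least 5 measured genes, without the sort markers that chose the cells, were tested with camera (correlation preset to 0.01), adjusted over the lists of each comparison. Camera with an estimated correlation and fry were alternatives. Counts adjusted over the list alone used the Benjamini-Hochberg method on the limma p of the list members. List levels per array are mean log2 values of the members minus the mean of the 6 normal group means.

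Genes named in the text followed a rule: the 6 largest increases and the 6 largest decreases among called genes whose arrays did not overlap between groups, without immunoglobulin and T-cell receptor segments and sort markers; up to 4 members of smallest p of each list described; and Bcl6, Myc and Yy1. Trp53 and Lig4 were not analysed here. Tumours were correlated (Pearson) with the mean of each normal stage over genes with an F-test adjusted p under 0.001 between stages. The tumour groups were compared by exact 2-sided permutation tests. Each normal array was placed in the same way, left out of the means, and also of the choice of genes, a test added after the data were seen.

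The fits were tested on simulated data with 200 changed genes, made with the measured mean and spread of each gene and with a spread of its own for each array as limma's array weights estimate it. Alternatives were the mean of all probe sets, a filter on dim genes, renewed quantile normalization, equal medians, a trended and robust prior, array weights, a fit on the compared groups alone, the replicate number as a block, covariates for strain or for the 3' minus 5' difference of Actb and Gapdh, and leaving out each array in turn. With 1 array left in a group, that array is assumed to vary like the other groups. Covariates for 18S rRNA and for the interquartile range, leaving out the 3 arrays of narrow spread, and leaving out 2 plasma cell arrays were added after the data were seen. A search for Yy1 motifs in promoters was left out because no genome sequence was used here. R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.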

Results

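Gene expression was measured on Affymetrix Mouse 430A2 arrays in 35 samples of mouse B cells and B-cell tumours, in 9 groups. The 22 arrays of sorted normal cells covered 6 stages of the B lineage. From bone marrow came pro-B cells (B220+, CD43-high, IgM-, n = 3), pre-B cells (B220+, CD43-low, IgM-, n = 3) and plasma cells (B220-low, Cd138+, Cd93-, n = 3). From spleen came transitional B cells (B220+, Cd93+, n = 4), germinal centre (GC) B cells (B220+, PNA-high, n = 5) and plasmablasts (B220+, Cd138+, Cd93-, n = 4). The 13 tumour arrays came from Bcl6 mice (n = 4), Myc/Bcl6 mice (n = 3) and mice lacking Lig4 and p53 (n = 6), and are called Bcl6, Myc/Bcl6-labelled and Lig4/p53 tumours. Pre-B and transitional cells came from strain 129, GC cells, plasmablasts and plasma cells from strain B6, and pro-B cells from both (2 arrays and 1 array), so that the step from transitional to GC cells was also a change of strain.

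Probe set intensities ran from 1.71 to 14.29 on the log2 scale, with a median of 4.921, and 12393 genes were compared. The number of arrays limits the precision. Control probe sets separated the arrays: the mean log2 intensity of the 18S rRNA probe sets was 10 to 11.3 in every sorted array except the plasma cells (4.02, 4.21 and 7.38), and 4.14 to 6.15 in the tumours. The 3' minus 5' log2 difference of Actb and Gapdh, which grows as RNA shortens, was 2.25 to 4.70 in tumours, 4.59 and 4.46 in plasma cell replicates 1 and 2, 0.451 in plasma cell replicate 3, and 0.68 to 2.95 in the other sorted arrays. Pro-B replicate 1, pre-B replicate 2 and Bcl6 tumour replicate 2 had a narrow spread of values, with an interquartile range of 2.09, 2.03 and 2.15. Next came the 3 tumours labelled Myc/Bcl6 (2.33 to 2.85), and all other arrays had 3.25 or more.

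**Figure D1:**
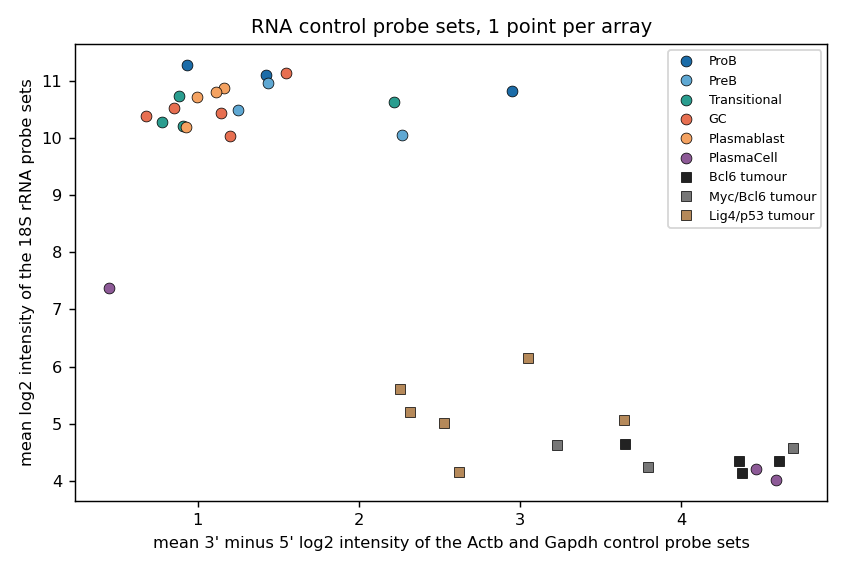
Mean log2 intensity of the 18S rRNA probe sets against the mean 3' minus 5' log2 difference of the Actb and Gapdh control probe sets, 1 point per array, coloured by group. The 13 tumours and plasma cell replicates 1 and 2 lie at low 18S rRNA (at most 6.15), where their 3' minus 5' difference is 2.25 or more.

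The comparison of pre-B with pro-B cells, the stages on both sides of heavy chain rearrangement, gave few changed genes: 14 were higher and 6 lower in pre-B cells (20 of 12393, n = 3 and 3, log2 difference ± SE throughout). Genes of red cell precursors were among the largest increases: Rhd (4.29 ± 0.77), a blood group antigen, Aqp1 (4.13 ± 0.79), a water channel, and Fech (3.19 ± 0.61), the last enzyme of heme synthesis. Also higher were Rsad2 (3.73 ± 0.62), an antiviral gene induced by interferon, Cdr2 (3.19 ± 0.56) and Pi16 (2.54 ± 0.49). Decreases were largest in Cd7 (-4.46 ± 0.69), a receptor of T and NK cells, Ccl4 (-3.11 ± 0.55), a chemokine, Eomes (-2.70 ± 0.40), a transcription factor of NK and T cells, Srm (-2.19 ± 0.45), which makes spermidine, Pcp4l1 (-1.90 ± 0.35) and Ctla2a (-1.80 ± 0.33).

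Mature B-cell genes had a median log2 difference of 0.692. Of 14 measured, 0 passed over all genes, 4 rose and 0 fell adjusted over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.00563, adjusted p = 0.572 with an estimated correlation). Early B-cell genes, with terminal transferase (Dntt) and the surrogate light chain (Vpreb1), had a median log2 difference of -0.458. Of 14 measured, 0 passed over all genes, 1 rose and 4 fell adjusted over the list alone, and 5 had an unadjusted p under 0.05 (camera adjusted p = 0.0112, adjusted p = 0.572 with an estimated correlation). Single members were Lef1 (-2.37 ± 0.52, adjusted p = 0.0635), Dntt (-3.30 ± 0.74, adjusted p = 0.0712), Vpreb1 (-3.41 ± 0.84, adjusted p = 0.113) and Cd40 (2.44 ± 0.61, adjusted p = 0.119). Lists of other cell types differed too. NK-cell markers had a median log2 difference of -0.96. Of 8 measured, 1 fell over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0202, adjusted p = 0.572 with an estimated correlation). T-cell markers had a median log2 difference of -0.306. Of 11 measured, 0 passed over all genes, 0 rose and 3 fell adjusted over the list alone, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.00563, adjusted p = 0.572 with an estimated correlation). Erythroid markers had a median log2 difference of 1.148. Of 8 measured, 0 passed over all genes, 4 rose and 0 fell adjusted over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p = 0.00811, adjusted p = 0.572 with an estimated correlation). Bcl6 (-1.07 ± 0.75, adjusted p = 0.557), Myc (0.83 ± 0.91, adjusted p = 0.72) and Yy1 (0.35 ± 0.56, adjusted p = 0.817) did not pass. In arrays simulated with the measured spread of each array, 92.6% of calls in this comparison were false, and limma on these 6 arrays alone called 0 genes (180 at an unadjusted p under 0.05). Called genes numbered 50 without pro-B replicate 1, 59 without pro-B replicate 3, 91 without pre-B replicate 1, 32 without pre-B replicate 2 and 87 without the 3 arrays of narrow spread (added after the data were seen, 29.4% of simulated calls false). Of called genes 70% were higher, and 53.5% after renewed quantile normalization, 57.6% with array weights (33 genes, 6 of them among the 20, with 7.7% of simulated calls false) and 55.2% without the arrays of narrow spread.

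From the pre-B to the transitional stage, mature B-cell and MHC class II genes rose and granulocyte markers fell. Of 724 called genes, 363 were higher and 361 lower in transitional cells (n = 4 and 3). The largest increases were in Cd83 (5.09 ± 0.39), a membrane protein of activated B cells, H2-Oa (4.89 ± 0.47) and H2-DMb2 (4.28 ± 0.48), which act in peptide loading of MHC class II, Cd274 (4.85 ± 0.49), the ligand PD-L1, Cr2 (4.41 ± 0.58), a complement receptor, and Fgd2 (4.18 ± 0.61). The largest decreases were in granule proteins of neutrophils and their precursors, Lcn2 (-7.06 ± 0.87), Camp (-6.76 ± 0.81), Ltf (-6.64 ± 0.61), Ngp (-6.27 ± 0.59) and Mpo (-6.21 ± 0.99), and in Cd177 (-6.24 ± 0.45), a neutrophil surface protein.

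Mature B-cell genes rose, among them Cd22 (3.72 ± 0.41), a brake on antigen receptor signalling, S1pr1 (3.55 ± 0.49), a receptor for exit from lymphoid tissue, and Cxcr5 (3.77 ± 0.52), a follicle homing receptor. Of 14 measured, 9 rose over all genes and 14 adjusted over the list alone (camera adjusted p = 4.18e-15, adjusted p = 0.00295 with an estimated correlation). MHC class II presentation genes followed, with H2-Eb1 (2.12 ± 0.30). Of 11 measured, 9 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 3.07e-13, adjusted p = 0.00295 with an estimated correlation). Early B-cell genes fell, as in Il7r (-3.64 ± 0.47), the interleukin-7 receptor, Rag2 (-3.0 ± 0.39), a recombinase subunit, Dntt (-3.99 ± 0.69) and Vpreb1 (-3.58 ± 0.79). Of 14 measured, 6 fell over all genes and 9 adjusted over the list alone (1 higher, 9 lower, camera adjusted p = 2.68e-07, adjusted p = 0.0562 with an estimated correlation). Mitosis genes fell, such as Aurkb (-4.36 ± 0.57), a kinase of chromosome segregation, and Tpx2 (-3.47 ± 0.72). Of 19 measured, 9 fell over all genes and 16 adjusted over the list alone (camera adjusted p = 6.69e-14, adjusted p = 0.169 with an estimated correlation). Of the DNA replication genes, Chaf1b (-3.32 ± 0.57) and Mcm3 (-1.52 ± 0.32) fell too. Of 20 measured, 3 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 1.7e-07, adjusted p = 0.238 with an estimated correlation). Immediate early genes, which stimulation and handling of cells induce, were higher, as in Atf3 (2.11 ± 0.44), Junb (2.23 ± 0.49) and Nr4a1 (3.75 ± 0.87). Of 13 measured, 5 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 9.23e-06, adjusted p = 0.238 with an estimated correlation). Higher NF-kB targets were Nfkb2 (1.82 ± 0.33) and Icam1 (2.03 ± 0.60). Of 15 measured, 3 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00931, adjusted p = 0.238 with an estimated correlation). Granulocyte markers were lower. Of 12 measured, 11 fell over all genes and 12 adjusted over the list alone (camera adjusted p = 3.4e-23, adjusted p = 0.00295 with an estimated correlation). Myc (2.93 ± 0.85, adjusted p = 0.0451) rose, while Bcl6 (1.93 ± 0.70, adjusted p = 0.116) and Yy1 (0.13 ± 0.53, adjusted p = 0.915) did not pass. Myc lost its call without any 1 of the 7 arrays (adjusted p = 0.058 to 0.103). Bcl6, low in pre-B replicate 2 (4.74, others 9.28 and 9.46), passed without replicate 1 or 3 (adjusted p = 0.0319 and 0.0295, range 0.0295 to 0.611). Of calls simulated with the measured spread 89.5% were false (1112 of 1243, more calls than the 724 measured). The measured count was 471 without transitional replicate 4 and 202 with the arrays of these 2 groups alone. It was 1734 without the 3 arrays of narrow spread, where 97% of simulated calls were false (4798 of 4946). With array weights, where 9.8% were false, 634 genes passed, 388 of them shared with the 724, and 31.5% were higher against 50.1%.

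GC cells are dividing B cells selected for affinity in the spleen, and 17 of 19 mitosis genes were higher in them than in transitional cells. Of 1673 called genes, 656 were higher and 1017 lower in GC cells (n = 5 and 4). The largest increases were in genes of cytotoxic lymphocytes and granulocytes: Gzma (5.36 ± 0.91), a granzyme, Ctsw (4.78 ± 0.56), a protease of NK and T cells, Ms4a4b (4.94 ± 0.57), a T-cell membrane protein, and Camp (5.20 ± 0.71), S100a8 (5.15 ± 0.83) and Ngp (5.00 ± 0.52) of neutrophils. Most lowered were Irs2 (-3.68 ± 0.53), an adaptor of insulin signalling, Pdia4 (-3.32 ± 0.59), an endoplasmic reticulum chaperone, Sik1 (-3.06 ± 0.51), a kinase, Mid1 (-2.76 ± 0.65), Cyp2c29 (-2.72 ± 0.32), a liver enzyme, and Cdh2 (-2.54 ± 0.30), N-cadherin.

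Mitosis genes rose with Aurkb (3.21 ± 0.51), Tpx2 (3.37 ± 0.63), Top2a (2.53 ± 0.50) and Nusap1 (3.33 ± 0.70). Of 19 measured, 17 rose over all genes and 18 adjusted over the list alone (camera adjusted p = 5.6e-17, adjusted p = 0.0934 with an estimated correlation). DNA replication genes also rose, among them the helicase subunits Mcm4 (2.73 ± 0.42) and Mcm6 (2.70 ± 0.51). Of 20 measured, 8 rose over all genes and 11 adjusted over the list alone (camera adjusted p = 3.4e-11, adjusted p = 0.0934 with an estimated correlation). Known germinal centre genes included Gcsam (3.91 ± 0.51), Mef2b (3.02 ± 0.43), a transcription factor, Fas (2.94 ± 0.45), the death receptor, and Pou2af1 (1.40 ± 0.30), a coactivator needed for germinal centres. Of 11 measured, 6 rose over all genes and 8 adjusted over the list alone (camera adjusted p = 1.98e-09, adjusted p = 0.00703 with an estimated correlation). In Polycomb repressive complex 2, the H3K27 methyltransferase, Mtf2 (3.64 ± 0.56), Rbbp7 (1.53 ± 0.39) and its catalytic subunit Ezh2 (1.85 ± 0.48) rose. Of 8 measured, 4 rose and 1 fell over all genes, 4 and 1 adjusted over the list alone (camera adjusted p = 0.00265, adjusted p = 0.274 with an estimated correlation). NK-cell markers were higher in GC cells, with Klrd1 (4.32 ± 0.43), Nkg7 (3.47 ± 0.46) and Klrk1 (3.30 ± 0.45). Of 8 measured, 7 rose over all genes and 7 adjusted over the list alone (7 higher, 1 lower, camera adjusted p = 1.48e-10, adjusted p = 0.00718 with an estimated correlation). T-cell markers rose with the receptor chains Cd3e (2.77 ± 0.28) and Cd3g (2.78 ± 0.44). Of 11 measured, 6 rose over all genes and 8 adjusted over the list alone (camera adjusted p = 3.42e-07, adjusted p = 0.0508 with an estimated correlation). Granulocyte markers went the same way, with Ltf (3.89 ± 0.54). Of 12 measured, 7 rose over all genes and 8 adjusted over the list alone (camera adjusted p = 1.69e-10, adjusted p = 0.0602 with an estimated correlation). Higher macrophage and dendritic cell markers were C1qc (2.43 ± 0.52) and Cd68 (1.92 ± 0.49). Of 14 measured, 7 rose over all genes and 7 adjusted over the list alone (7 higher, 1 lower, camera adjusted p = 9.47e-06, adjusted p = 0.0934 with an estimated correlation). The Yy1 and INO80 complex list had a median of -0.249 while its test pointed up without passing. Of 11 measured, 1 rose over all genes and 1 adjusted over the list alone (camera adjusted p = 0.56, adjusted p = 0.847 with an estimated correlation). The called member was Ino80c (1.56 ± 0.33). Myc (-2.36 ± 0.75, adjusted p = 0.0407) fell, while Bcl6 (1.47 ± 0.62, adjusted p = 0.118) and Yy1 (0.98 ± 0.46, adjusted p = 0.165) did not pass. With array weights, in these 2 groups alone and without the arrays of narrow spread, Bcl6 passed (adjusted p = 0.000124, 0.00128 and 0.000149, range 0.000124 to 0.918 over all alternatives), as did Yy1 (0.00303, 0.0083 and 0.00156, range 0.00156 to 0.998). Myc no longer passed without any 1 of transitional replicates 1 to 4 or GC replicates 1 to 4 (adjusted p = 0.0693 to 0.0942). The median log2 difference of all genes was -0.27 and moved to -0.061 after renewed quantile normalization (920 genes called, 55.2% of them higher against 39.2%) and to -0.092 with equal medians (63.1% higher). With strain as a covariate 40 genes passed, and leaving out transitional replicate 1 or 2 or GC replicate 1 or 2 gave 949, 941, 1030 and 990.

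Plasmablasts, the dividing precursors of plasma cells, differed from GC cells in few genes: 15 were higher and 69 lower (84 called, n = 4 and 5). The chaperone Pdia4 (3.64 ± 0.59) rose most. The other large increases were in the liver transcripts Alb (2.42 ± 0.28) and Apoa2 (2.36 ± 0.47), in Car3 (2.13 ± 0.47), a carbonic anhydrase, Septin8 (2.11 ± 0.48) and Atp1b2 (1.87 ± 0.40), none of which exceeded a mean of 7.16 in plasmablasts. The largest decreases were in the GC-associated genes Gcsam (-3.47 ± 0.51) and Fas (-3.04 ± 0.45), the NK-cell genes Klrd1 (-3.68 ± 0.43), Ctsw (-3.37 ± 0.56) and Xcl1 (-3.06 ± 0.41), and Parm1 (-3.21 ± 0.43).

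Of the germinal centre genes, Pou2af1 (-1.46 ± 0.30) fell as well. Of 11 measured, 3 fell over all genes and 8 adjusted over the list alone (camera adjusted p = 1.02e-15, adjusted p = 0.000304 with an estimated correlation). NK-cell markers fell, with Klrk1 (-2.90 ± 0.45) and Ncr1 (-2.50 ± 0.42). Of 8 measured, 4 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 1.33e-14, adjusted p = 0.00132 with an estimated correlation). T-cell markers were also lower, with Cd3e (-1.69 ± 0.28), Cd3g (-2.11 ± 0.44) and Cd8a (-2.14 ± 0.48). Of 11 measured, 3 fell over all genes and 6 adjusted over the list alone (camera adjusted p = 2.78e-08, adjusted p = 0.0284 with an estimated correlation). Macrophage and dendritic cell markers were lower as a list although single members did not pass. Of 14 measured, 0 passed over all genes, 0 rose and 6 fell adjusted over the list alone, and 7 had an unadjusted p under 0.05 (camera adjusted p = 2.74e-08, adjusted p = 0.0299 with an estimated correlation). Mitosis genes had a median log2 difference of -1.058. Of 19 measured, 0 passed over all genes, 0 rose and 0 fell adjusted over the list alone, and 4 had an unadjusted p under 0.05 (camera adjusted p = 2.34e-08, adjusted p = 0.272 with an estimated correlation). For the ER and secretory pathway, the machinery of antibody secretion, Pdia4 was the called member. Of 25 measured, 1 rose over all genes and 1 adjusted over the list alone (camera adjusted p = 0.00665, adjusted p = 0.641 with an estimated correlation). Sdf2l1 (1.97 ± 0.64, adjusted p = 0.198), Creld2 (1.7 ± 0.66, adjusted p = 0.337), Bcl6 (-1.83 ± 0.62, adjusted p = 0.224), Myc (1.59 ± 0.75, adjusted p = 0.508) and Yy1 (-0.56 ± 0.46, adjusted p = 0.909) did not pass. Again with array weights, in these groups alone and without the arrays of narrow spread, Bcl6 passed (adjusted p = 1.12e-06, 0.00113 and 0.000154, range 1.12e-06 to 0.525 over all alternatives), and so did Myc (0.0003, 0.0397 and 0.0391, range 0.0003 to 0.876). Yy1 passed in the first 2 of these (0.0361 and 0.0373, range 0.0361 to 1). Called genes numbered 38, 33 and 41 without GC replicates 1, 2 and 3, and 32, 49 and 31 without plasmablast replicates 1, 2 and 3. They numbered 1679 in a fit of these 9 arrays alone. The excess of decreases depended on the fit: 17.9% of the 84 were higher, but 55.3% of 3010 with array weights and 40.5% of 845 without the arrays of narrow spread.

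Bone marrow plasma cells, which secrete antibody, differed from plasmablasts in 1771 genes, 1103 higher and 668 lower (n = 3 and 4). The largest increases were in AF067061 (6.25 ± 0.85), Slc47a1 (6.16 ± 0.56), a transporter, Tnfsf9 (5.61 ± 0.37), the ligand of 4-1BB, Spats2 (5.60 ± 0.40), Prickle1 (5.52 ± 0.52), a planar polarity protein, and Cth (5.47 ± 0.46), an enzyme of cysteine synthesis. The granulocyte proteins S100a8 (-7.68 ± 0.95) and S100a9 (-7.00 ± 0.73) fell most, followed by Satb1 (-6.96 ± 0.92), a chromatin organiser of lymphocytes, Fos (-6.66 ± 0.90), Dpp4 (-6.58 ± 0.67) and Arhgef18 (-6.21 ± 0.93). Bcl6 (-5.76 ± 0.70, adjusted p = 6.2e-06) fell from 9.39 ± 0.31 to 3.62 ± 0.18 (mean ± SD), and Myc (0.45 ± 0.85, adjusted p = 0.813) and Yy1 (-0.08 ± 0.53, adjusted p = 0.952) did not pass. With 18S rRNA as a covariate Bcl6 did not pass (-4.28, adjusted p = 0.342, range 7.87e-15 to 0.342 over all alternatives).

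Of the mitosis genes, Bub1 (2.77 ± 0.86), Kif11 (1.74 ± 0.56) and Cdc20 (2.28 ± 0.76) rose. Of 19 measured, 3 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.553 with an estimated correlation). Their level was 0.79 in plasma cells (arrays 0.66 to 0.86) and -0.49 in plasmablasts (-1.63 to 0.06). The DNA replication list, at 0.56 against -0.35, did not pass, with Chaf1b (2.38 ± 0.57) and Cdc45 (1.88 ± 0.54) higher. Of 20 measured, 3 rose over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0527, adjusted p = 0.578 with an estimated correlation). Mature B-cell genes fell with Klf2 (-5.81 ± 0.43), Cd37 (-3.43 ± 0.32) and Cr2 (-5.58 ± 0.58). Of 14 measured, 8 fell over all genes and 8 adjusted over the list alone (camera adjusted p = 5.69e-12, adjusted p = 0.0231 with an estimated correlation). In MHC class II presentation, H2-DMb2 (-5.0 ± 0.48), H2-Eb1 (-1.55 ± 0.30) and H2-DMa (-2.84 ± 0.60) fell and the co-stimulator Cd80 (2.35 ± 0.52) rose. Of 11 measured, 2 rose and 7 fell over all genes, 2 and 7 adjusted over the list alone (camera adjusted p = 0.000117, adjusted p = 0.0957 with an estimated correlation). Immediate early genes fell with Zfp36 (-4.33 ± 0.35) and Egr2 (-2.65 ± 0.54). Of 13 measured, 9 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 6.25e-10, adjusted p = 0.0957 with an estimated correlation). Glycolysis genes rose with Ldha (1.74 ± 0.34) and Tpi1 (2.21 ± 0.45). Of 11 measured, 8 rose over all genes and 8 adjusted over the list alone (camera adjusted p = 0.000857, adjusted p = 0.364 with an estimated correlation). Of the oxidative phosphorylation genes, Uqcrc2 (2.37 ± 0.34) and Ndufv2 (2.32 ± 0.40) rose. Of 25 measured, 5 rose over all genes and 6 adjusted over the list alone (camera adjusted p = 0.02, adjusted p = 0.548 with an estimated correlation). The list of plasma cell genes did not pass, with Derl3 (-3.20 ± 0.50) and Slamf7 (-1.75 ± 0.42) lower. Of 13 measured, 2 fell over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0535, adjusted p = 0.456 with an estimated correlation). Sdc1, the gene of the Cd138 antigen used in the sort, averaged 4.73 ± 0.92 in plasma cells against 8.75 ± 2.23 in plasmablasts (5.52 in replicate 4). Cd93 averaged 7.34 ± 1.14 in plasma cells, sorted as Cd93-, and 6.48 ± 1.35 in transitional cells, sorted as Cd93+. These transcripts did not bear out the sort labels, which stay in doubt. Granulocyte markers were lower in plasma cells, with Ngp (-4.96 ± 0.59). Of 12 measured, 7 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 9.77e-12, adjusted p = 0.0755 with an estimated correlation). The median of all genes was 0.222 and became 0.108 after renewed quantile normalization. With 18S rRNA as a covariate, which the plasma cell arrays had at 4.02 to 7.38 and plasmablasts at 10.2 to 10.9, 110 genes passed, and leaving out plasma cell replicate 1 or 2 gave 1141 and 1143.

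Against the mean of the 5 other normal stages, 881 genes were higher and 1114 lower in GC cells (1995 called, n = 5 and 17). The largest increases, in every GC array above every other normal array, were in Fscn1 (4.44 ± 0.46), an actin bundling protein, Gcsam (4.15 ± 0.39), a GC signalling adaptor, Basp1 (3.81 ± 0.43), Klrd1 (3.69 ± 0.33), an NK receptor chain, Slc41a2 (3.47 ± 0.40), a magnesium transporter, and Lpxn (3.41 ± 0.39). Lowest in GC cells in the same sense were Car3 (-1.92 ± 0.36), Dennd1a (-1.80 ± 0.24), 1700037H04Rik (-1.69 ± 0.32), Ccdc86 (-1.67 ± 0.28), B4galt6 (-1.67 ± 0.28) and Uqcrq (-1.65 ± 0.32), a subunit of respiratory complex III. Bcl6 (3.33 ± 0.47, adjusted p = 9.97e-05), the repressor that directs the germinal centre reaction, rose, and Myc (-0.81 ± 0.57, adjusted p = 0.305) and Yy1 (0.95 ± 0.35, adjusted p = 0.0678) did not pass. Yy1 passed without pro-B replicate 2 (adjusted p = 0.0442) or pre-B replicate 1, 2 or 3 (adjusted p = 0.0462, 0.0416 and 0.039), and Myc without pro-B replicate 1 (adjusted p = 0.0273), with array weights (0.00204) or without the arrays of narrow spread (0.0152), in a range of 0.00204 to 0.508 over all alternatives.

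Known germinal centre genes were higher, with Fas (2.98 ± 0.34), Pou2af1 (1.77 ± 0.23) and Mef2b (2.50 ± 0.33). Of 11 measured, 9 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 8.92e-12, adjusted p = 0.00154 with an estimated correlation). Mature B-cell genes rose with Cr2 (3.57 ± 0.39) and Ms4a1 (3.00 ± 0.48), but their level was 1.23 (transitional cells 1.61). Of 14 measured, 10 rose over all genes and 11 adjusted over the list alone (camera adjusted p = 2.02e-10, adjusted p = 0.0116 with an estimated correlation). MHC class II genes rose too (1.06, transitional cells 1.10), with H2-Aa (1.55 ± 0.18) and H2-DMb2 (2.52 ± 0.32). Of 11 measured, 8 rose over all genes and 10 adjusted over the list alone (camera adjusted p = 1.13e-09, adjusted p = 0.00585 with an estimated correlation). In Polycomb repressive complex 2, Mtf2 (2.88 ± 0.43) and Suz12 (1.18 ± 0.24) were called. Of 8 measured, 2 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00114, adjusted p = 0.223 with an estimated correlation). T-cell markers were higher, with Cd3e (2.84 ± 0.21) and Cd3g (2.87 ± 0.33). Of 11 measured, 7 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 4.46e-08, adjusted p = 0.0188 with an estimated correlation). NK-cell markers were higher, with Klrk1 (2.97 ± 0.34). Of 8 measured, 7 rose over all genes and 7 adjusted over the list alone (7 higher, 1 lower, camera adjusted p = 2.08e-10, adjusted p = 0.00585 with an estimated correlation). The median of all genes was -0.238 and moved to -0.101 after renewed quantile normalization (958 called, 59.6% of them higher against 44.2%) and to -0.103 with equal medians (68.9% higher), while 30.1% were higher with array weights and 30.9% without the arrays of narrow spread, and 247 genes passed with strain as a covariate. The count was 3065 without pre-B replicate 2, and 1054, 1074, 1127, 1204 and 1238 without GC replicates 1 to 5.

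Genes higher in GC cells than in each of the 5 other stages (adjusted p < 0.05 and a log2 difference of at least 1 in all 5 comparisons) numbered 24, against 1 in pro-B cells, 11 in pre-B cells, 10 in transitional cells, 1 in plasmablasts and 449 in plasma cells. By the smallest of the 5 differences, the first were Gcsam (3.47), Lpp (2.49), a focal adhesion protein, Ly75 (2.19), the endocytic receptor DEC-205, Klrd1 (2.15), Fas (2.13), Cd3g (2.11), Klrc1 (2.04), an NK receptor, Dck (1.90), a kinase of nucleotide salvage, Mcm4 (1.89) and Klrk1 (1.88). Tox (1.46), a T-cell transcription factor, Cd3e (1.69) and Pou2af1 (1.40) were also among the 24. Klrd1, Klrk1, Cd3g and Cd3e belong to the fixed lists of NK and T cells. The number was 7 with strain as a covariate, 92 without the 3 arrays of narrow spread, 52 and 65 without pro-B replicate 1 and pre-B replicate 2, 13, 13 and 37 without GC replicates 1, 2 and 5, and 13 and 12 without plasmablast replicates 1 and 3.

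Bcl6 was highest in GC cells, at 11.22 ± 0.36 (mean log2 intensity ± SD, n = 5), and lowest in plasma cells, at 3.62 ± 0.18 (n = 3), and it lay at 7.17 ± 0.97 in Bcl6 tumours (n = 4) and 6.68 ± 2.46 in Myc/Bcl6-labelled tumours (n = 3). Myc was highest in Lig4/p53 tumours (10.91 ± 0.47, n = 6) and transitional cells (10.84 ± 0.16, n = 4) and lowest in Myc/Bcl6-labelled tumours (5.15 ± 0.24, n = 3). Yy1, the zinc finger factor named in the title of the series, averaged 10.37 ± 0.22 in GC cells and 8.92 to 9.81 in the other normal stages by the probe set of highest mean. By its 3 other probe sets it was not highest in GC cells, with 7.47, 7.68 and 4.39 there against 8.51, 8.05 and 5.01 in transitional cells. Whether the Bcl6 and Myc probe sets detect the altered genes is not stated in the labels, which call the Bcl6 mice both transgenic and knock-in, and an exchange of tumour labels was not excluded. Neither Trp53 nor Lig4 was analysed here.

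**Figure D2:**
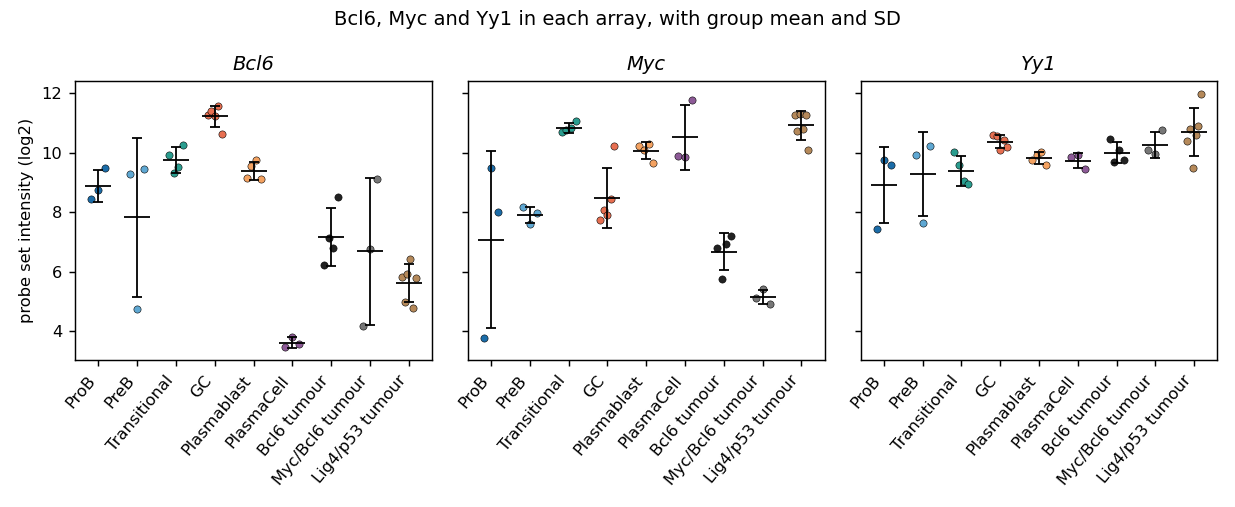
Log2 probe set intensity of Bcl6, Myc and Yy1 in each array (points) by group, with group mean and SD (bars). Bcl6 is highest in the GC group (mean 11.22) and Myc lowest in the tumours labelled Myc/Bcl6 (mean 5.15), while Yy1 group means run from 8.92 to 10.69.

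**Figure D3:**
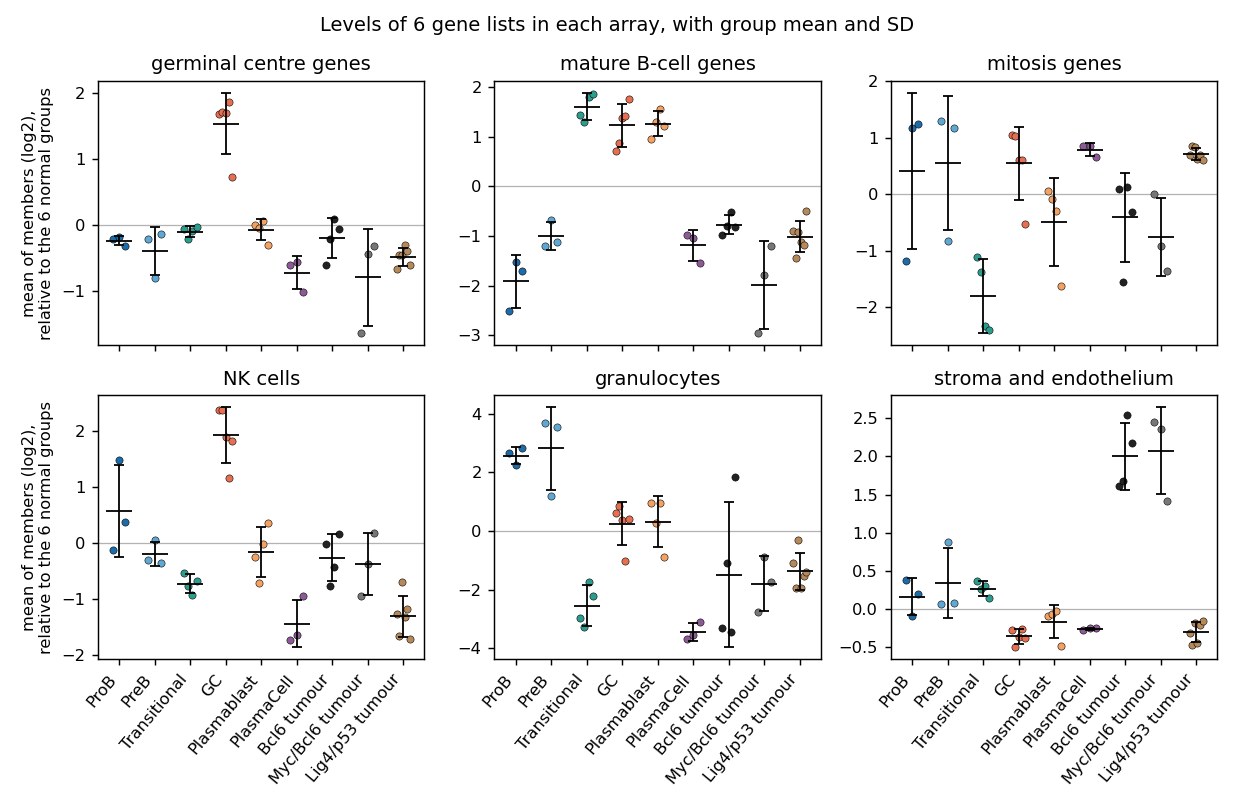
Mean log2 level of 6 fixed gene lists in each array (points), relative to the mean of the 6 normal groups, with group mean and SD (bars). Germinal centre genes (1.54 ± 0.46) and NK-cell markers (1.92 ± 0.50) are highest in GC cells, granulocyte markers in pro-B and pre-B cells (2.58 ± 0.29 and 2.82 ± 1.40), and stromal markers in Bcl6 and Myc/Bcl6-labelled tumours (2.00 ± 0.44 and 2.07 ± 0.57).

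GC cells had the highest Bcl6 of the normal stages. Against them Bcl6 tumours had 1607 genes higher and 1719 lower (3326 called, n = 4 and 5). The largest increases were in genes induced by interferon-gamma, Cxcl9 (8.07 ± 0.50), a chemokine, and Iigp1 (6.87 ± 0.53), a GTPase, in Clu (6.79 ± 0.74), clusterin, Ccl8 (6.18 ± 0.60), a chemokine, Igfbp7 (5.59 ± 0.35), a secreted protein of vessels, and Cfb (5.35 ± 0.46), complement factor B. Lowest against GC cells were Fos (-5.65 ± 0.76) and Zfp36 (-5.13 ± 0.43), immediate early genes, Cr2 (-5.46 ± 0.51), Pold4 (-5.39 ± 0.65), a DNA polymerase subunit, Gzma (-5.23 ± 0.81) and Vasp (-5.19 ± 0.50), an actin regulator. Bcl6 (-4.05 ± 0.70, adjusted p = 6.63e-05) itself fell, as did Myc (-1.81 ± 0.64, adjusted p = 0.0334), and Yy1 (-0.37 ± 0.45, adjusted p = 0.556) did not pass. Myc no longer passed without GC replicate 4 or 5 (adjusted p = 0.0507 and 0.118) or Bcl6 tumour replicate 1 or 2 (adjusted p = 0.0557 and 0.133). Bcl6 did not pass with the 3' minus 5' difference (-3.21, adjusted p = 0.0532) or 18S rRNA (-1.89, adjusted p = 0.8) as a covariate, in a range of 2e-08 to 0.8 over all alternatives.

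Markers of stroma and endothelium rose, with the matrix genes Col4a1 (4.46 ± 0.41), Sparc (4.67 ± 0.46) and Dcn (3.89 ± 0.45). Of 13 measured, 10 rose and 1 fell over all genes, 10 and 1 adjusted over the list alone (camera adjusted p = 1.56e-07, adjusted p = 0.0201 with an estimated correlation). Macrophage and dendritic cell markers rose with Csf1r (4.35 ± 0.57) and C1qb (3.71 ± 0.61). Of 14 measured, 5 rose over all genes and 5 adjusted over the list alone (camera adjusted p = 0.0393, adjusted p = 0.501 with an estimated correlation). Genes known to be repressed by Bcl6 were higher, with Cxcl10 (3.99 ± 0.58), Tlr7 (4.34 ± 0.74) and Cdkn1a (2.24 ± 0.62). Of 12 measured, 5 rose over all genes and 6 adjusted over the list alone (6 higher, 1 lower, camera adjusted p = 0.0393, adjusted p = 0.43 with an estimated correlation). The interferon response list did not pass, with Oasl2 (3.85 ± 0.44) and Rtp4 (2.15 ± 0.52) higher. Of 12 measured, 4 rose and 1 fell over all genes, 4 and 1 adjusted over the list alone (camera adjusted p = 0.0526, adjusted p = 0.546 with an estimated correlation). Germinal centre genes fell, among them Gcsam (-4.78 ± 0.45) and Spib (-3.02 ± 0.59). Of 11 measured, 7 fell over all genes and 8 adjusted over the list alone (camera adjusted p = 6.17e-05, adjusted p = 0.0405 with an estimated correlation). Mature B-cell genes fell, with Cd37 (-3.89 ± 0.35) and Cd55 (-3.66 ± 0.50). Of the 14 measured, 7 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 1.31e-06, adjusted p = 0.0471 with an estimated correlation). The median of all genes was 0.212, and 0.124 after renewed quantile normalization. With 18S rRNA as a covariate (4.14 to 4.65, GC cells 10 to 11.1) 1 gene passed. With the 3' minus 5' difference 872 passed.

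Tumours labelled Myc/Bcl6 differed from GC cells in 5960 genes, 3365 higher and 2595 lower (n = 3 and 5). Interferon-gamma targets again stood high, Cxcl9 (6.06 ± 0.55) and Iigp1 (5.96 ± 0.57), beside Fabp1 (6.56 ± 1.00), a fatty acid binding protein of the liver (9.12 ± 4.17, mean ± SD, with 13.54 in replicate 2 against at most 8.54 in any other array), Cp (5.63 ± 0.67), ceruloplasmin, Fkbp9 (6.34 ± 0.37), a chaperone, and Gsto1 (5.93 ± 0.44), a glutathione transferase. Most lowered were the actin regulators Vasp (-6.58 ± 0.55) and Pfn1 (-5.99 ± 0.62), Klf6 (-6.28 ± 0.86), Ranbp9 (-6.16 ± 0.62), and the B-cell surface genes Cd37 (-6.00 ± 0.39) and Ly6d (-5.97 ± 0.53). Bcl6 (-4.54 ± 0.76, adjusted p = 2.74e-05) and Myc (-3.33 ± 0.69, adjusted p = 0.000327), the genes that name these tumours, both fell. Yy1 (-0.10 ± 0.49, adjusted p = 0.87) did not pass. Myc lost its call with the 3' minus 5' difference (-1.76, adjusted p = 0.12), the interquartile range (-1.68, adjusted p = 0.0836) or 18S rRNA (-0.90, adjusted p = 0.82) as a covariate (range 3.62e-07 to 0.82 over all alternatives), and Bcl6 with 18S rRNA (-2.41, adjusted p = 0.543, range 4.58e-07 to 0.543).

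Mature B-cell genes fell (median -2.755, -2.026 without replicate 1), among them Cr2 (-5.86 ± 0.56) and Ccr6 (-4.29 ± 0.55). Of 14 measured, 14 fell over all genes and 14 adjusted over the list alone (camera adjusted p = 2.2e-09, adjusted p = 0.0242 with an estimated correlation). MHC class II genes fell (median -3.464, -2.728 without replicate 1), with H2-Oa (-5.16 ± 0.54) and Cd74 (-3.60 ± 0.44). Of 11 measured, 1 rose and 8 fell over all genes, 1 and 8 adjusted over the list alone (camera adjusted p = 9.32e-06, adjusted p = 0.112 with an estimated correlation). NF-kB targets fell with Cflar (-4.96 ± 0.38) and Cd83 (-4.84 ± 0.64). Of 15 measured, 9 fell over all genes and 10 adjusted over the list alone (camera adjusted p = 6.25e-05, adjusted p = 0.11 with an estimated correlation). Among germinal centre genes Gcsam (-4.38 ± 0.49) and Spib (-4.43 ± 0.64) were lower. Of 11 measured, 7 fell over all genes and 8 adjusted over the list alone (camera adjusted p = 2.65e-05, adjusted p = 0.0265 with an estimated correlation). Markers of stroma and endothelium rose with Igfbp7 (5.57 ± 0.38) and Col4a1 (4.46 ± 0.45). Of 13 measured, 8 rose and 1 fell over all genes, 8 and 1 adjusted over the list alone (camera adjusted p = 4.11e-05, adjusted p = 0.0532 with an estimated correlation). Plasma cell genes went both ways, with Zbtb20 (-2.70 ± 0.34) and Irf4 (-5.09 ± 1.06) lower and Tnfrsf17 (1.67 ± 0.37) higher. Of 13 measured, 4 rose and 3 fell over all genes, 4 and 3 adjusted over the list alone (camera adjusted p = 0.855, adjusted p = 0.925 with an estimated correlation). Their median was 0.694, while the mean was -0.217 and the test pointed down. The median of all genes was 0.31 and became 0.187 after renewed quantile normalization. With 18S rRNA as a covariate (4.24 to 4.62 in these tumours, 10 to 11.1 in GC cells) 238 genes passed. The interquartile range was 2.33 to 2.85 in these tumours and 3.95 to 4.14 in GC cells, and 22.9% of simulated calls were false.

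Lig4/p53 tumours were set against pro-B cells, whose V(D)J recombination uses the DNA end joining ligase Lig4. Of 2613 called genes, 1633 were higher and 980 lower (n = 6 and 3). The largest increases were in Lmo7 (5.16 ± 0.60), Reln (4.75 ± 0.80), reelin, Mtm1 (4.57 ± 0.57), a lipid phosphatase, Hepacam2 (4.39 ± 0.56), Cenpv (4.34 ± 0.40), a centromere protein, and Sbf2 (4.32 ± 0.44). The pro-B genes Dntt (-7.61 ± 0.55) and Vpreb1 (-6.73 ± 0.69) fell most, followed by Camp (-6.07 ± 0.91) of granulocytes, Cd7 (-5.83 ± 0.61), and the red cell genes Hbb-b2 (-5.59 ± 0.75), a beta globin, and Car2 (-5.46 ± 0.66). Myc (3.83 ± 0.67, adjusted p = 0.000129) and Yy1 (1.77 ± 0.47, adjusted p = 0.00751) rose and Bcl6 (-3.27 ± 0.74, adjusted p = 0.0018) fell. Yy1 did not pass without pro-B replicate 1 (1.03, adjusted p = 0.187), without the arrays of narrow spread (0.0541) or in these groups alone (0.0654), in a range of 0.00241 to 0.613 over all alternatives. With 18S rRNA as a covariate none of the 3 passed (adjusted p = 0.274 for Myc, range 5.09e-06 to 0.274, 0.613 for Yy1, and 0.971 for Bcl6, range 6.61e-08 to 0.971).

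Ribosome biogenesis genes, many of them known targets of Myc, rose with Cad (4.2 ± 0.66), Ncl (1.94 ± 0.32) and Nop56 (2.12 ± 0.36). Of 18 measured, 10 rose over all genes and 16 adjusted over the list alone (camera adjusted p = 2.36e-07, adjusted p = 0.185 with an estimated correlation). Oxidative phosphorylation genes went up with Sdhd (2.54 ± 0.30) and Uqcrc2 (2.44 ± 0.29). Of 25 measured, 9 rose over all genes and 11 adjusted over the list alone (11 higher, 1 lower, camera adjusted p = 0.000136, adjusted p = 0.419 with an estimated correlation). Early B-cell genes fell, with Lef1 (-4.36 ± 0.42). Of 14 measured, 7 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 8.78e-05, adjusted p = 0.118 with an estimated correlation). The p53 target list did not pass, with Aen (1.24 ± 0.45) higher. Of 14 measured, 1 rose over all genes and 0 adjusted over the list alone (camera adjusted p = 0.747, adjusted p = 0.842 with an estimated correlation). Granulocyte markers were lower, with Mmp9 (-3.29 ± 0.53). Of 12 measured, 10 fell over all genes and 11 adjusted over the list alone (camera adjusted p = 8.24e-09, adjusted p = 0.118 with an estimated correlation). NK-cell markers were lower too, with Eomes (-2.87 ± 0.38). Of 8 measured, 7 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 1.93e-05, adjusted p = 0.0867 with an estimated correlation). The median of all genes was -0.065 and moved to 0.13 with equal medians (76.1% of called genes higher against 62.5%, but 50.6% with array weights and 47.5% without the arrays of narrow spread). With 18S rRNA as a covariate (4.15 to 6.15 in these tumours, 10.8 to 11.3 in pro-B cells) 4 genes passed, and the count was 1511 without pro-B replicate 1.

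Bcl6 and Myc/Bcl6-labelled tumours differed in 484 genes, 240 higher and 244 lower in the tumours labelled Myc/Bcl6 (n = 3 and 4). The largest increases were in genes of the liver: Apoa1 (3.80 ± 0.81), an apolipoprotein, Fgb (3.63 ± 0.94), fibrinogen, Itih4 (3.60 ± 0.91), Ambp (3.59 ± 0.96), Tfr2 (3.57 ± 0.90), an iron sensor, and Ugt2b5 (3.42 ± 0.91), a detoxifying enzyme. Their levels came mainly from replicate 2, in which albumin (Alb) reached 13.99 against at most 6.83 in any other array. Genes most lowered were Serpinb6b (-3.94 ± 0.80), Chst1 (-3.42 ± 0.61), Gimap3 (-3.42 ± 0.72), a GTPase of lymphocytes, Glipr1 (-3.38 ± 0.62), Sh3bgrl3 (-3.36 ± 0.60) and St3gal6 (-3.32 ± 0.81).

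MHC class II presentation genes fell, with Cd74 (-2.87 ± 0.46), H2-Ab1 (-3.15 ± 0.55), H2-Eb1 (-2.46 ± 0.45) and Ciita (-2.73 ± 0.59), the class II transactivator. Of 11 measured, 6 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 1.67e-08, adjusted p = 0.0873 with an estimated correlation). NF-kB targets fell with Nfkbie (-2.87 ± 0.64) and Nfkb2 (-1.67 ± 0.38). Of 15 measured, 5 fell over all genes and 11 adjusted over the list alone (camera adjusted p = 5.61e-06, adjusted p = 0.0873 with an estimated correlation). Mature B-cell genes were also lower, with Cd37 (-2.11 ± 0.40), Fcgr2b (-2.64 ± 0.56), an inhibitory Fc receptor, and the kinase Blk (-2.79 ± 0.60). Of 14 measured, 5 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.0873 with an estimated correlation). Myc (-1.52 ± 0.72, adjusted p = 0.245), Bcl6 (-0.48 ± 0.80, adjusted p = 0.796) and Yy1 (0.27 ± 0.51, adjusted p = 0.828) did not differ past the threshold (Myc passed without the arrays of narrow spread, where 71% of simulated calls were false, adjusted p = 0.00683, range 0.00683 to 0.483 over all alternatives), and the germinal centre list did not pass either, with Irf8 (-2.86 ± 0.52) lower. Of 11 measured, 1 fell over all genes and 1 adjusted over the list alone (camera adjusted p = 0.108, adjusted p = 0.558 with an estimated correlation). Replicate 1 of the tumours labelled Myc/Bcl6 stood apart, with Ptprc, the CD45 gene, at 7.12 against 10.47 and 11.38 in the others and Ighm at 5.61 against 11.74 and 13.03. Their MHC class II level ran from -2.83 in it to -0.27. Without it the median went from -1.996 to -1.045 in the MHC class II list and from -1.331 to -1.0 in the mature B-cell list. The called genes were 49.6% higher, and 39% with equal medians and 30% with array weights. In arrays simulated with the measured spread 42.9% of calls were false, and limma on these 7 arrays alone called 0 genes (1218 at an unadjusted p under 0.05). The count was 1386, 119 and 136 without Bcl6 tumour replicates 2, 3 and 4, and 234 and 780 without Myc/Bcl6-labelled replicates 2 and 3.

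Lig4/p53 tumours differed from Bcl6 tumours in 3271 genes, 1916 higher and 1355 lower (n = 6 and 4). Their 3' minus 5' differences did not overlap (2.25 to 3.64 and 3.65 to 4.60). Increases were largest in Sox4 (5.32 ± 0.68), a transcription factor of B-cell progenitors, Akap12 (5.95 ± 0.59), a kinase scaffold, Nav2 (5.81 ± 0.41), Enpep (4.76 ± 0.51), an aminopeptidase of B-cell precursors, Trib2 (4.73 ± 0.61) and Myl4 (4.62 ± 0.83). Myc (4.24 ± 0.61, adjusted p = 5.07e-06) was higher as well. The largest decreases were in Cxcl9 (-8.04 ± 0.48), Cxcl13 (-5.87 ± 0.57), a chemokine of follicles, Clu (-7.47 ± 0.72), Iigp1 (-7.15 ± 0.51), Jchain (-6.62 ± 0.70), the joining chain of secreted antibody, and Igfbp7 (-5.96 ± 0.34). Bcl6 (-1.55 ± 0.67, adjusted p = 0.0854) and Yy1 (0.69 ± 0.43, adjusted p = 0.243) did not pass. Bcl6 passed with the mean of probe sets, array weights, these groups alone, without the arrays of narrow spread and with the interquartile range as a covariate (adjusted p = 0.0441, 0.00652, 0.0155, 0.0434 and 0.017, range 0.00652 to 0.266 over all alternatives), and Yy1 with the mean of probe sets (0.0246, range 0.0246 to 0.884).

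Early B-cell genes rose with Myb (3.19 ± 0.42) and Vpreb3 (4.15 ± 0.58). Of 14 measured, 6 rose and 1 fell over all genes, 6 and 1 adjusted over the list alone (camera adjusted p = 0.000874, adjusted p = 0.184 with an estimated correlation). Ribosome biogenesis genes rose with Polr1b (2.85 ± 0.41) and Nop56 (1.79 ± 0.33). Of 18 measured, 14 rose over all genes and 14 adjusted over the list alone (camera adjusted p = 6.21e-07, adjusted p = 0.184 with an estimated correlation). DNA replication genes went up with Mcm3 (1.67 ± 0.34) and Chaf1b (2.17 ± 0.47). Of 20 measured, 10 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 4.21e-05, adjusted p = 0.247 with an estimated correlation). The Yy1 and INO80 complex list, of chromatin remodelling proteins, included Mcrs1 (1.78 ± 0.39) and Ino80e (1.61 ± 0.45). Of 11 measured, 5 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 0.00268, adjusted p = 0.247 with an estimated correlation). Plasma cell genes were lower, with Ell2 (-5.43 ± 0.51), an elongation factor for antibody secretion, and Zbtb20 (-2.78 ± 0.30). Of 13 measured, 1 rose and 7 fell over all genes, 2 and 7 adjusted over the list alone (camera adjusted p = 0.000874, adjusted p = 0.155 with an estimated correlation). Bcl6-repressed genes fell with Cxcl10 (-4.35 ± 0.55) and Tlr7 (-5.04 ± 0.71). Of 12 measured, 7 fell over all genes and 7 adjusted over the list alone (camera adjusted p = 0.000858, adjusted p = 0.155 with an estimated correlation). Markers of stroma and endothelium, with Col4a1 (-4.18 ± 0.40) and Dcn (-4.06 ± 0.43), were lower. Of 13 measured, 1 rose and 9 fell over all genes, 1 and 10 adjusted over the list alone (camera adjusted p = 1.31e-08, adjusted p = 0.00815 with an estimated correlation). Macrophage and dendritic cell markers fell with C1qb (-3.95 ± 0.58) and Csf1r (-3.53 ± 0.55). Of the 14 measured, 7 fell over all genes and 9 adjusted over the list alone (camera adjusted p = 4.21e-05, adjusted p = 0.155 with an estimated correlation). Of called genes 58.6% were higher, and 48.7% after renewed quantile normalization. The count was 2072 without Bcl6 tumour replicate 2, 1 of the arrays of narrow spread.

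Against the tumours labelled Myc/Bcl6, Lig4/p53 tumours had 2870 genes higher and 2761 lower (5631 called, n = 6 and 3). Myc (5.76 ± 0.67, adjusted p = 1.88e-07) was 1 of the largest increases, although it names the other tumours. The others were Trib2 (6.13 ± 0.66), Sox4 (5.33 ± 0.75), Crip1 (5.67 ± 0.44), Bcat1 (5.35 ± 0.77), a branched-chain aminotransferase and known Myc target, and Ptprs (5.22 ± 0.49), a receptor phosphatase. The largest decreases were in Clu (-6.29 ± 0.78), Iigp1 (-6.25 ± 0.55), Fkbp9 (-6.08 ± 0.35), Cxcl9 (-6.02 ± 0.53), Igfbp7 (-5.93 ± 0.37) and Ell2 (-5.46 ± 0.56). Bcl6 (-1.06 ± 0.74, adjusted p = 0.23) and Yy1 (0.42 ± 0.47, adjusted p = 0.466) did not pass, but Bcl6 passed without Myc/Bcl6-labelled replicate 1 (adjusted p = 0.0143) or with the mean of probe sets (0.0434), in a range of 0.0143 to 0.895 over all alternatives, and Yy1 with the latter (0.0209, range 0.0209 to 0.791).

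Mitosis genes rose with Kif11 (3.00 ± 0.48) and Birc5 (3.24 ± 0.71). Of 19 measured, 11 rose over all genes and 12 adjusted over the list alone (camera adjusted p = 0.00139, adjusted p = 0.438 with an estimated correlation). DNA replication genes followed, with Mcm3 (2.63 ± 0.37) and Tk1 (3.06 ± 0.51). Of 20 measured, 13 rose over all genes and 14 adjusted over the list alone (camera adjusted p = 0.000799, adjusted p = 0.438 with an estimated correlation). Ribosome biogenesis genes were also higher, with Rrs1 (3.62 ± 0.62) and Fbl (2.06 ± 0.41). Of 18 measured, 14 rose over all genes and 15 adjusted over the list alone (camera adjusted p = 9.5e-05, adjusted p = 0.438 with an estimated correlation). Early B-cell genes were higher, with Myb (5.19 ± 0.46) and Il7r (4.12 ± 0.55). Of 14 measured, 7 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 0.0111, adjusted p = 0.438 with an estimated correlation). Markers of stroma and endothelium fell with Col4a1 (-4.18 ± 0.43) and Col1a2 (-3.82 ± 0.49). Of 13 measured, 9 fell over all genes and 10 adjusted over the list alone (camera adjusted p = 1.45e-05, adjusted p = 0.0657 with an estimated correlation). The median of all genes was -0.156 and moved to -0.049 with equal medians. In arrays simulated with the measured spread 29.2% of calls were false, and the count was 3718 without Myc/Bcl6-labelled replicate 3.

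To place the tumours among normal stages, each tumour array was correlated across 904 genes that differed between the stages with each stage mean (genes are not independent replicates). Left out in turn of the means and of the choice of genes, 19 of 22 normal arrays correlated best with their own stage. Pro-B replicates 1 and 3 correlated best with pre-B cells and plasmablast replicate 4 with transitional cells. With the 904 genes, which the array left out had helped to choose, all 22 did. Of the 13 tumours, 12 correlated best with plasma cells, with a mean r of 0.233 ± 0.115 (SD, n = 4) in Bcl6 tumours, 0.279 ± 0.141 (n = 3) in Myc/Bcl6-labelled tumours and 0.235 ± 0.034 (n = 6) in Lig4/p53 tumours. Bcl6 tumour replicate 4 correlated best with GC cells (r = 0.106). Over the 496 stage signature genes, 449 of them of plasma cells, this changed: 2 of the 13 tumours correlated best with plasma cells, and the 6 Lig4/p53 tumours with plasmablasts. The plasma cell list, with Xbp1, Irf4 and Prdm1, lay below the mean of the normal stages in all 6 Lig4/p53 tumours (-0.99 ± 0.20). It averaged 0.47 in Bcl6 tumours, 0.09 in Myc/Bcl6-labelled tumours and 0.19 in plasma cells. The difference r(GC) minus r(pro-B) was 0.136 ± 0.167 in Bcl6, -0.088 ± 0.164 in Myc/Bcl6-labelled and -0.027 ± 0.099 in Lig4/p53 tumours. No pair of tumour groups differed in it by an exact 2-sided permutation test: Bcl6 against Myc/Bcl6-labelled p = 0.171 (35 splits, smallest possible 0.0571, so that it could not reach 0.05), Bcl6 against Lig4/p53 p = 0.114 (210 splits) and Myc/Bcl6-labelled against Lig4/p53 p = 0.548 (84 splits), adjusted for 3 tests to 0.256, 0.256 and 0.548.

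**Figure D4:**
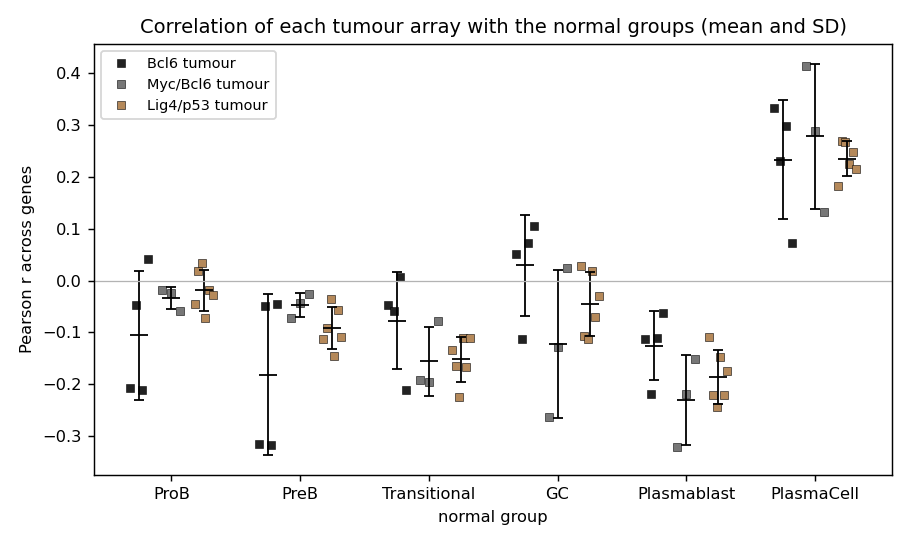
Pearson correlation across genes of each tumour array (squares) with the mean of each normal group, with the mean and SD of each tumour group. Values for plasma cells (group means 0.233 to 0.279) lie above those for the other stages in 12 of the 13 tumours.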

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

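Arrays far from the others of their group were sought in groups of 4 to 6 arrays with Dixon's test, which picks about 1 in 20 sets by chance, and 15 of 162 sets were picked. Of the tests below, those of strain, of plasma cell differentiation and of other cell types and the cell cycle were chosen only after the result was seen.

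GC replicate 5 had more Myc (10.23, others 7.75 to 8.44). Its levels of germinal centre genes (0.72, others 1.68 to 1.87), mitosis genes (-0.54, others 0.6 to 1.04) and Polycomb repressive complex 2 (0.42, others 0.72 to 0.8) were lower. GC replicate 4 was low in granulocyte markers (-1.0, others 0.38 to 0.87). Transitional replicate 4 had a 3' minus 5' difference of Actb and Gapdh of 2.21, against 0.78 to 0.91 in the others. Plasmablast replicate 4 was low in oxidative phosphorylation (-0.68, others 0.07 to 0.08), glycolysis (-0.59, others 0.06 to 0.14) and stroma (-0.49, others -0.09 to -0.02), and high in megakaryocyte markers (-0.16, others -0.33 to -0.31). Bcl6 tumour replicate 2 was low in DNA replication (-1.15, others -0.15 to 0.04) and ribosome biogenesis (-1.36, others 0.14 to 0.21). Bcl6 tumour replicate 4 was high in macrophage and dendritic cell markers (3.40, others 1.47 to 1.75). Lig4/p53 tumour replicate 6 was high in glycolysis (1.73, others 0.43 to 0.77) and megakaryocyte markers (1.01, others -0.4 to -0.16).

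Transcripts of T and NK cells were high in the GC arrays. A difference between the strains B6 and 129 was argued against, since the NK list lay 2.08 higher in GC cells than in plasmablasts, which were B6 cells from spleen as well. T or NK cells among the sorted cells are a candidate source: in a second set of 17 T and NK markers, 6 were called higher in GC than in transitional cells, Ccl5, Cd27, Cd96, Tbx21, Fyb and Sh2d1a. The set left out 2 genes of the fixed lists and 4 seen before it was written (10 of 23 with these), a choice made after the count was known. Both shares lay between those set as bounds for and against it, so that it cannot be told apart from expression in GC cells themselves. The B220 gate should remove most T cells, and no biological explanation was tested.

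Most tumours correlated best with plasma cells, which shared with them low 18S rRNA and, in 2 of 3 arrays, a high 3' minus 5' difference. Plasma cell differentiation was argued against in Lig4/p53 tumours, where the highest level of the plasma cell list was -0.75. Without genes of other cell types and the cell cycle, 13 of 13 tumours still correlated best with plasma cells. The genes of these lists were therefore not the whole cause. With the 18S rRNA slope removed from every gene it was 13 tumours, and with the 3' minus 5' slope removed 12. These slopes were fitted with a term for each group, so that a shift between groups stayed in the values. Neither trend could therefore be excluded as the whole cause, and both may contribute. The mean r with plasma cells fell to 0.211 in Bcl6, 0.26 in Myc/Bcl6-labelled and 0.167 in Lig4/p53 tumours with the 18S rRNA slope removed. With the 3' minus 5' slope removed it fell to 0.101, 0.179 and 0.161, and Bcl6 tumour replicate 4 correlated best with pro-B cells (r = 0.126). Over stage signature genes alone the Lig4/p53 tumours correlated best with plasmablasts, and r(GC) minus r(pro-B) became 0.089. Another property of RNA or preparation shared by tumours and plasma cells may contribute, and was not tested.

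Liver transcripts were high in Myc/Bcl6-labelled tumour replicate 2. Liver tissue in that sample may be the source: 23 of 24 measured liver markers were higher there than in any other array by at least 1 log2 unit, with Alb at 13.99 against at most 6.83. The exception was Hamp (2.99). A liver site of that tumour and liver taken with it stay open, and no biological explanation was tested.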

How the results depend on the processing

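Results without the 3 arrays of narrow spread, with the interquartile range or 18S rRNA as a covariate, and without 2 plasma cell arrays were chosen after the data were seen. The values below are counts of called genes that moved by more than 1.5 times, and the cause was not tested unless stated. Of counts and correlations under alternatives other than leaving out 1 array, 125 stayed within bounds and 61 did not. Of the genes named, 3921 values kept their side of the threshold, 285 lost the call, 47 gained it and 3 reversed. A reversal was counted only where the gene was called before or after the change. Changes of direction in genes called in neither fit are among the 3921. These 3 reversals came with the 18S rRNA covariate: H2-DMa (0.51, adjusted p = 0.938) and Cd80 (-0.61, adjusted p = 0.91) in plasma cells against plasmablasts, and Myc (0.67, adjusted p = 0.947) in Bcl6 tumours against GC cells. There Myc (-1.81) lost its call at -1.38 after quantile normalization, -1.56 with the block, -0.05 with the 3' minus 5' covariate and -0.85 with the interquartile range, and it was -1.99 to -1.37 with 1 array left out (adjusted p = 0.00871 to 0.981 over all alternatives). Yy1 in GC cells against the mean of the other stages passed with equal medians (adjusted p = 0.0348), array weights (0.00164) and without the narrow arrays (0.00599), in a range of 0.00164 to 0.941 over all alternatives. Bcl6 in that comparison did not pass with strain (adjusted p = 0.0614, range 5.83e-11 to 0.0614 over all alternatives).

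Pre-B against pro-B cells called 20 genes, and 48 with the mean of probe sets, 43 after quantile normalization, 33 with array weights, 8 with a replicate block, 34 with the 3' minus 5' covariate, 59 with strain, 87 without the narrow arrays and 190 with the interquartile range. The 2 groups alone gave 0 in limma (180 at an unadjusted p under 0.05), with fewer arrays to estimate spread. Transitional against pre-B cells called 724, and 202 in the groups alone, 455 with the block, 1734 without the narrow arrays (97% of simulated calls false) and 1859 with the interquartile range.

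GC against transitional cells called 1673, and 1069 with the filter (fewer genes tested), 920 after quantile normalization, 5614 with array weights, 5286 in the groups alone, 1073 with the block, 40 with strain, 5139 without the narrow arrays and 2857 with the interquartile range. Plasmablasts against GC cells called 84, and 152 with equal medians, 3010 with array weights, 1679 in the groups alone, 143 with the 3' minus 5' covariate, 845 without the narrow arrays and 397 with the interquartile range. Plasma cells against plasmablasts called 1771, and 6245 with array weights, 3308 in the groups alone, 4029 without the narrow arrays, 3077 with the interquartile range, 110 with 18S rRNA and 731 with 1 plasma cell array left. GC cells against the mean of the other stages called 1995, and 958 after quantile normalization, 6274 with array weights, 929 with the block, 247 with strain and 4739 without the narrow arrays. GC signature genes numbered 24, and 53 with equal medians, 69 with array weights, 42 with the 3' minus 5' covariate, 7 with strain, 92 without the narrow arrays, 55 with the interquartile range and 7 with 18S rRNA.

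Bcl6 tumours against GC cells called 3326, and 5010 with array weights, 872 with the 3' minus 5' covariate and 1 with 18S rRNA. Myc/Bcl6-labelled tumours against GC cells called 5960, and 2922 with the 3' minus 5' covariate, 3251 with the interquartile range and 238 with 18S rRNA. Lig4/p53 tumours against pro-B cells called 2613, and 4456 with array weights and 4 with 18S rRNA. 18S rRNA separates tumours from these sorted cells as the labels do, and the 3' minus 5' difference nearly so. Myc/Bcl6-labelled against Bcl6 tumours called 484, and 0 in the groups alone (1218 at an unadjusted p under 0.05), 256 with the block and 3701 without the narrow arrays (71% of simulated calls false). Lig4/p53 against Bcl6 tumours called 3271 and, with array weights, 4921. Lig4/p53 against Myc/Bcl6-labelled tumours called 5631, and 3534 after quantile normalization and 2415 with the interquartile range. The r(GC) minus r(pro-B) of Lig4/p53 tumours was -0.027, and 0.089 over stage signature genes. Of 312 list tests 147 passed with camera, 120 with fry and 22 with an estimated correlation.

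Leaving out 1 array in turn gave 18 to 91 genes for pre-B against pro-B cells, 471 to 1054 for transitional against pre-B cells, 941 to 1437 for GC against transitional cells, 31 to 110 for plasmablasts against GC cells, 1141 to 1843 for plasma cells against plasmablasts, 1054 to 3065 for GC cells against the mean, and 12 to 65 signature genes. For tumours it gave 2334 to 3296 (Bcl6 against GC), 4568 to 5566 (Myc/Bcl6-labelled against GC), 1511 to 3225 (Lig4/p53 against pro-B), 119 to 1386 (Myc/Bcl6-labelled against Bcl6), 2072 to 3404 (Lig4/p53 against Bcl6) and 3718 to 5606 (Lig4/p53 against Myc/Bcl6-labelled). The r differences were 0.086 to 0.203, -0.174 to -0.01 and -0.05 to -0.003. The Yy1 motif search was not run. Signal over background limits dim genes.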

Other observations

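Other splits of the arrays of each comparison into groups of the same sizes were counted, a test planned for each. Where more than 100 exist, 100 were drawn. Of the splits run, the labelled one alone (1 of them) reached its own count, which argued against chance, in 9 comparisons. These were GC against transitional cells (1673 genes, highest other split 370), plasmablasts against GC cells (84, 48), plasma cells against plasmablasts (1771, 282) and GC cells against the mean of the other stages (1995, 517). Among tumours they were Bcl6 against GC (3326, 1377), Myc/Bcl6-labelled against GC (5960, 317), Lig4/p53 against pro-B (2613, 310), Lig4/p53 against Bcl6 (3271, 1227) and Lig4/p53 against Myc/Bcl6-labelled (5631, 1193). It could also be excluded for the 24 GC signature genes (highest other 0).

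In transitional against pre-B cells too only the labelled split reached its 724 genes (highest other 74). Arrays simulated with the measured spread gave 1112 false calls of 1243 there, so that noise was not excluded for this count. With array weights, where 16 of 163 simulated calls were false, 634 genes were called, 388 of them among the 724.

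Chance could not be excluded for Myc/Bcl6-labelled against Bcl6 tumours, where 6 of 35 splits called at least 484 genes. The highest other called 1741 by setting Bcl6 replicates 1, 3 and 4 apart, which points to a structure of the samples. Pre-B against pro-B cells allowed 10 splits, too few for a share under 0.05. There 5 called at least the 20 genes of the labels, and the highest other, with 4198, points to a structure of the samples as well.

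Taken alone, plasma cell replicate 3, which had a low 3' minus 5' difference, correlated with 12 of 13 tumours better than any other stage did. Its r was lower than that of replicates 1 and 2 in 13 of 13.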
